A study of Mus musculus with 2 samples.

How the data were processed

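RNA from the colonic epithelium of mice with colitis, induced by dextran sulfate sodium (DSS), was measured on 1-colour Agilent expression arrays. DSS is a detergent-like polysaccharide that injures the colonic epithelium when given to mice. There were 2 arrays, 1 per genotype. Each array carried RNA combined from 3 mice, per the labels' extraction protocol, so mouse-to-mouse spread cannot be read from either array. Samples were assigned to the wild-type or knockout group by the genotype given in their labels.

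The authors deposited 1 table of normalized log2 signals, with 1 value per probe and array for 41267 probes. The submitters' processing notes name Agilent Feature Extraction 10.7. The background correction, the normalization method and any flag filter are not given in the sources used here. The log base is not stated either and was taken from the values, which ran from 1.53 to 19.2. A natural log would put the brightest probe at 2.20e+08 units, against 605413 units for base 2. The sorted values of the arrays were identical at 99.3% of ranks, and the widest gap between values of equal rank was 0.000514. The arrays had therefore been brought to 1 common distribution before deposit, which removes any overall difference in signal between them. The median was 5.72 on both arrays. No per-probe centring was present, and a positive difference means a higher signal in the knockout pool. Scanner output, detection flags and spot-level values were not used here.

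The design fixed before the data were examined was written for genes: a check of Tsc1, 44 lists of pathway and cell type genes, and a rule for naming genes. The table identifies its rows by probe ID only. None of these IDs occurs in the gene table used for names (0 matches), and no gene was guessed from an ID. The level of Tsc1, the lists and the summaries over probes of a gene were therefore not computed, and every count below is of probes. Several probes can target 1 gene, so a count of probes is not a count of genes. The rule for naming genes (the 12 largest differences each way, list members and set genes such as Car1) could not be applied. The 2 probes with the largest difference in each direction are named by ID instead. These were taken from the filtered probes that lay over background on both arrays.

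Of the 41267 probes, 93 had control names and were left out of the comparison, which left 41174 mouse probes. Probes entered the comparison if their mean over both arrays was at or above the median of all mouse probes (5.67 on the log2 scale), which left 20587. The log2 difference was the knockout value minus the wild-type value, and differences of at least 1 on the log2 scale (2-fold) were counted. With 1 array per genotype there is no test and no p-value. The number of arrays limits the precision of every value. Background was set, after the data were seen, at the highest signal among 27 control probes (the negative control, the dark corner and the RC and ETG series). That signal was 2.09 on the wild-type array and 2.29 on the knockout array, and the higher value was used for both. A probe at or below it on 1 array has only a bound there. Its fold is then computed against 2.29 and written as "at least".

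Other settings chosen beforehand were centring each array on its median, a common 75th percentile, quantile normalization, removal of a loess trend on mean signal (fraction 0.3), no signal filter, and filters at the lower and the upper quartile. Settings chosen after seeing the data were scaling the arrays to equal E1A spike-in signal and raising dim values to the background level. The counting step was tested on simulated arrays made from the wild-type values with the spread of the bright control probes. It recovered 47 of 50 probes changed by 1.3 on the log2 scale, 50 of 50 changed by 2.0, 50 of 50 changed by 3.0 and 3 of 50 changed by 0.8. It counted 0 unchanged probes among the 20587 in the step. The simulated noise had an SD of 0.12 at every signal, so at a threshold of 1 that outcome was fixed in advance. The SD over the filtered mouse probes, real differences included, was 0.85 in the dimmest of 5 groups by signal and 0.41 in the brightest. The 0 thus gives no rate of false counts for these arrays. The changed probes were drawn only from signals well over the filter. The simulation holds no animal-to-animal spread. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.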

Results

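Colon epithelial cells were profiled in mice whose Tsc1 gene was deleted in the epithelium of the cecum and colon, and in wild-type mice. Tsc1 encodes a subunit of the complex that restrains the growth-regulating kinase complex mTORC1, so its loss is known to raise mTORC1 activity. The deletion relied on Cre recombinase expressed from the carbonic anhydrase 1 promoter in mice carrying a floxed Tsc1 gene. All mice received 3% DSS for 7 days before the cells were harvested, and RNA of 3 mice was combined for each genotype. The design thus gave 1 wild-type pool and 1 knockout pool, both with colitis, and no untreated pool was analysed here. The stated purpose of the series was to find mRNAs regulated through mTORC1 in the inflamed colon epithelium. The table compares genotypes and does not measure mTORC1 activity. No replicate spread exists for any value below. The probes carried no gene names in the sources used here, so the level of Tsc1 itself could not be given and the genotype labels were not checked against the targeted gene.

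Most of the brighter mouse probes differed by less than 2-fold between the knockout and wild-type pools. This held for 19225 of the 20587 probes over the signal filter. In the knockout pool 731 probes (3.55%) were at least 2-fold higher and 631 probes (3.07%) were at least 2-fold lower. Higher probes made up 53.7% of the 1362 probes that were at least 2-fold apart. The counts depended on the filter. With the lower-quartile filter 2339 of 30880 probes were higher and 2244 lower, without a filter 2475 of 41174 were higher and 2418 lower, and with the upper-quartile filter 189 of 10294 were higher and 190 lower. The split between higher and lower depended on scaling. With the arrays set to equal E1A spike-in signal, which lowered every knockout value by 0.13 on the log2 scale, 575 probes were higher and 869 lower, so higher probes made up 39.8%. The lowest mean signal of an E1A probe over the filter was 8.59, where the difference was 0.07. Mouse probes were most often 2-fold apart below that signal, so an offset of 0.13 need not hold there. The median log2 difference was -0.03, with lower and upper quartiles of -0.27 and 0.23. Across the filtered probes, which are not independent replicates, Pearson's r between the pools was 0.972 and Spearman's rho was 0.970.

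**Figure D1:**
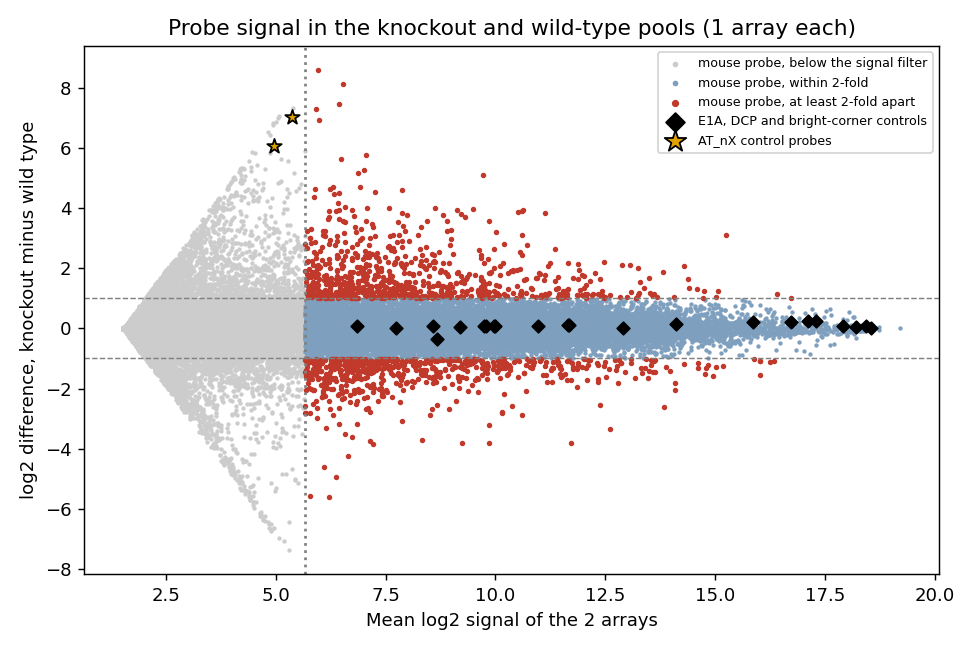
Difference in log2 signal between the knockout and wild-type pools (vertical axis) against the mean log2 signal of both arrays (horizontal axis), with 1 point per probe and 1 array per pool. The dotted line is the signal filter at 5.67 and dashed lines mark 2-fold differences. Red points are the 731 higher and 631 lower probes, diamonds are the 22 bright control probes, and stars are the AT_nX control probes, drawn at 6.05 and 7.04. The wild-type signals of the AT_nX probes lie below background, so taken against the background level these differences are at least 5.70 and 6.61.

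Among probes over the mean-signal filter, large differences were more often increases than decreases in the knockout pool. At least 4-fold, 209 probes were higher and 92 were lower. At least 8-fold, 79 probes were higher and 19 were lower. With equal spike-in signal the 8-fold counts were 66 higher and 21 lower, so this direction did not depend on that scaling. Without the signal filter they were 327 higher and 239 lower, a smaller imbalance. These unfiltered counts include folds against deposited values below background, which are not measured folds. Bright probes with signal over background in 1 pool alone, of which only 2 passed the filter, showed no such excess of increases. There were 90 in the knockout pool and 104 in the wild-type pool, a nearly even split. The number of genes behind these probes is unknown.

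The largest increase among probes over background on both arrays was at A_52_P267391, with a log2 signal of 2.47 in the wild-type pool and 10.6 in the knockout pool, a 280-fold difference. The next was at A_51_P340456, with 2.71 and 10.2, a 177-fold difference. The largest decrease was at A_52_P89335, with 9.03 in the wild-type pool and 3.42 in the knockout pool, 49.0-fold lower. It was followed by A_52_P30728, with 8.57 and 2.99, 47.8-fold lower. Each of these rests on 1 array per genotype and on a dimmer signal close to background. For the increases that signal lay 0.18 and 0.43 log2 units over the background level, and for the decreases 1.13 and 0.71, in the order named.

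Some probes lay over the background level in only 1 of the pools. A probe just over that level on 1 array and just under it on the other is included. Of all 41174 mouse probes, 28829 lay over background in both pools and 8387 in neither. The knockout pool alone had signal over background at 1978 probes, and the wild-type pool alone at 1980. These numbers are nearly equal by construction, since 1 background level was applied to arrays that share 1 distribution of values. Among these, 90 probes reached at least the filter value of 5.67 in the knockout pool and were thus at least 10.4-fold higher there. In the wild-type pool 104 probes did so and were at least 10.4-fold lower in the knockout pool. The brightest knockout-only probe was at least 250-fold higher, and the brightest wild-type-only probe was at least 104-fold lower. Nearly all of these probes fell below the signal filter because it was set on the mean of both arrays, and only 2 entered the counts above.

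The share of probes apart by at least 2-fold fell with signal. The filtered probes were divided by signal into 5 groups of equal size. In the dimmest group (mean log2 signal 5.67 to 7.13), 6.92% were higher and 6.00% were lower. In the brightest group (11.7 to 19.2), 1.38% were higher and 1.65% were lower. That brightest group still held 57 probes at least 2-fold higher and 68 at least 2-fold lower. The standard deviation of the log2 difference over probes was 0.85 in the dimmest group and 0.41 in the brightest.

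**Figure D2:**
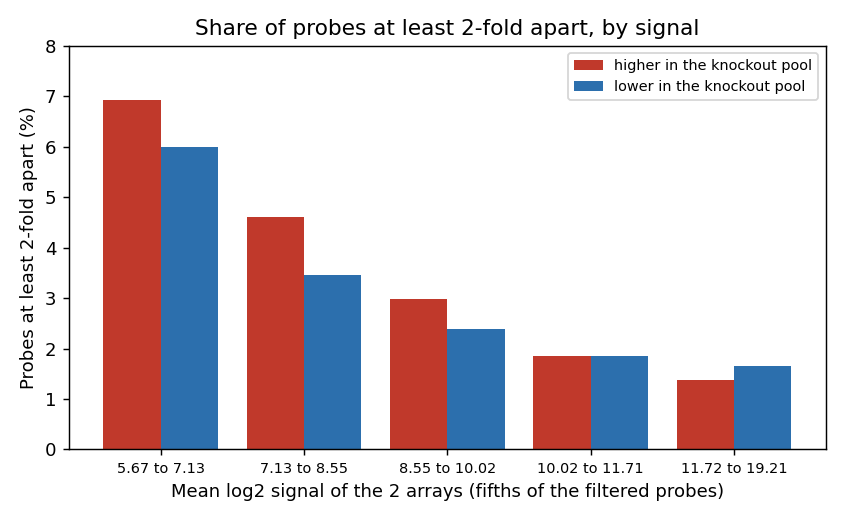
Percentage of filtered mouse probes at least 2-fold higher (red) or lower (blue) in the knockout pool, in 5 groups of equal size ordered by mean log2 signal of the 2 arrays. The percentages fall from 6.92% and 6.00% in the dimmest group to 1.38% and 1.65% in the brightest.

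Control probes gave the only available measure of technical spread. The 22 E1A, DCP and bright-corner control probes over the filter differed by 0.08 ± 0.12 on the log2 scale (mean ± SD over probes), with a range from -0.34 to 0.26. The lower end of that range was DCP_22_6 alone, and the next lowest difference was 0.0, at E1A_r60_1. The SD also holds a rise of the E1A differences with signal, from 0.07 to 0.26 below the brightest of them. Of the filtered mouse probes 8853 (43.0%) lay outside the range from -0.34 to 0.26. The controls were not matched to the mouse probes on signal. Only DCP_22_7 and DCP_20_5, with mean log2 signals of 6.84 and 7.74, lay under 8.55, where mouse probes were most often at least 2-fold apart. The 43.0% is therefore not a share of probes beyond technical spread. These controls do not pass through the animal or the RNA extraction, so their spread is not the spread between mice or between pools.

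Some control probes came in pairs, named with the endings 3 and 5. The members of each AT_ssM pair differed between pools in the same direction. Both AT_ssM_PC probes were lower in the knockout pool, by 2.13-fold and 2.35-fold, and both AT_ssM_TR probes were lower by 1.44-fold and 1.66-fold. The AT_ssM_AB probes were 1.21-fold and 1.43-fold higher, and both AT_ssM_GD probes were 1.17-fold higher. The AT_ssM_RR probes, near the top of the scale, differed by -0.01 and -0.03 on the log2 scale. With equal spike-in signal every one of the AT_ssM differences would be 0.13 lower on the log2 scale. AT_ssM_GD_3, at a mean log2 signal of 16.8, differed by 0.23. That is no more than controls of like signal, with 0.21 at DCP_1_7 and 0.26 at E1A_r60_n9. AT_ssM_GD_5, at 13.1, differed by 0.22, above the 0.01 of the bright corner at 12.9. Among the dim AT_n pairs, the AT_nC probes differed by -0.57 and 0.70 on the log2 scale and AT_nB_5 by 0.78. AT_nB_3 and AT_nD_3 lay below background on the wild-type array and were at least 1.36-fold and 1.28-fold higher in the knockout pool. AT_nD_5 lay barely over background in the wild-type pool, at 2.37, and below it in the knockout pool, at 1.62. The targets of these probes are not given in the sources used here, so it is not known whether they report transcripts of the mice or controls added to the RNA, and their folds cannot be read as technical spread.

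**Figure D3:**
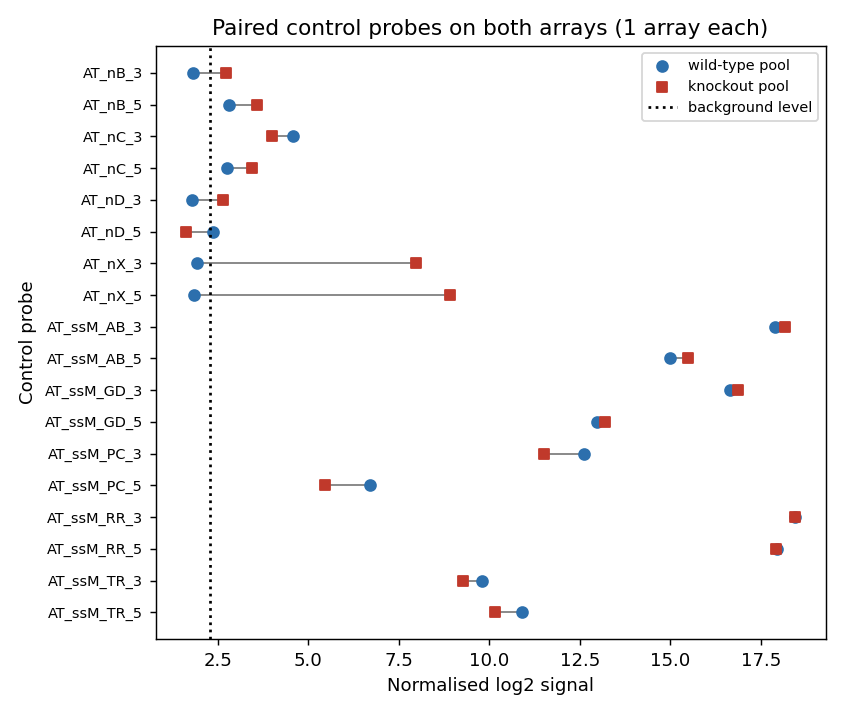
Normalised log2 signal (horizontal axis) of the AT_n and AT_ssM control probes (vertical axis) in the wild-type pool (blue circles) and the knockout pool (red squares), 1 array each, with the background level of 2.29 as a dotted line. The AT_nX probes lie at 1.93 and 1.86 in the wild-type pool and at 7.98 and 8.90 in the knockout pool.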

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

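The tests in this part were chosen only after the signals had been seen, except the loess test, which was fixed before the data were examined. A pair of control probes outside the comparison, AT_nX_3 and AT_nX_5, stood out because they had signal on the knockout array and none over background on the wild-type array. AT_nX_3 had a log2 signal of 1.93 in the wild-type pool and 7.98 in the knockout pool, at least 51.9-fold higher. AT_nX_5 had 1.86 and 8.90, at least 97.9-fold higher. A fault of a single spot would have raised 1 probe, and the smaller of both log2 differences, at AT_nX_3, was 6.05 as deposited. Its wild-type value lay below background, so taken against the background level this difference is at least 5.70. The pair was picked because both probes were raised, so this check could not have come out otherwise and adds no evidence of its own. A control RNA or mixture added to 1 array only stays open. The other 6 AT_n probes had a median difference of 0.74 and a range of -0.75 to 0.90. AT_nB_3, AT_nD_3 and AT_nD_5 lay below background on 1 array, so both ends of that range are not measured differences, and the median depends on them. Such values would count against a control mixture only if these probes reported the same mixture, and their names alone do not show that. What the pair targets is not given in the sources used here. By the form of their names the AT probes could belong to a control set that mixes mouse transcripts with foreign ones, which no source used here settles and which would change what their folds mean. A transcript carried by the knockout mice alone, such as the Cre transgene that the labels place only in these mice, stays open as a hypothesis with no test of its own. That the 2 probes lay at background on the wild-type array and over the filter on the knockout array is what singled them out, so it does not bear on this explanation. A mouse transcript that differs between the pools, or RNA present in 1 preparation, stays open as well.

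The 1362 probes at least 2-fold apart were also weighed against technical explanations. A trend of the difference on mean signal, left in the deposited values, was too small to be the cause. The fitted loess trend lay between -0.06 and 0.01 on the log2 scale over the filtered probes, against differences of at least 1. That 96.48% of these probes stayed at least 2-fold apart in the same direction after its removal follows from that size and adds no evidence. This reaches only a bias that normalization had left behind. Differences between the mice that were pooled, unrelated to genotype, cannot be told apart from the effect of the genotype, because there was 1 array per genotype. A different share of other cell types in the preparations, planned as a test with marker genes, was not tested because the probes have no gene names here.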

How the results depend on the processing

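The counts of probes at least 2-fold apart depended mainly on the signal filter. Without a filter 2475 probes were higher and 2418 lower, with the lower-quartile filter 2339 and 2244, and with the upper-quartile filter 189 and 190, against 731 and 631. These filters test different numbers of probes (41174, 30880 and 10294 against 20587) and admit or remove dim signals. Dim signals were counted there at their deposited values, without the background bound. Median centring, a common 75th percentile and quantile normalization changed either count by at most 2 probes, as they must on arrays that already share 1 distribution, so they say nothing about stability. Removing the loess trend gave 777 higher and 584 lower, and raising dim values to background gave 732 and 631. Both counts under equal spike-in signal, an alternative chosen after seeing the data like the raising of dim values, stayed within 1.5 times. There the split turned from mostly higher to mostly lower because 1 constant, 0.13 on the log2 scale, is taken from every knockout value, which moves probes across both thresholds by construction. The E1A probes did not show that offset at every signal. Among probes that passed the filter in use, more probes were at least 4-fold and at least 8-fold higher than lower under all 9 alternatives. The narrowest 8-fold ratio was 327 to 239, without a filter and with the lower-quartile filter, and the upper-quartile filter left 11 to 4. The named probes and the AT_nX pair kept their direction wherever they were recomputed. Their differences were far larger than any shift these settings make, so a reversal was not possible and this says nothing about stability. The upper-quartile filter gave no value for the named probes, and the AT_nX pair was recomputed only for centring, the 75th percentile, spike-in scaling and the background level. Alternatives for Tsc1, for the gene lists and for combining the probes of a gene were not run, because probes could not be assigned to genes. No replicate could be left out with 1 array per genotype. No paired analysis was possible with 1 array per genotype, and the replicate number that the pools share does not pair them. Signal over background limits the dim probes, where a fold is a bound.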

Other observations

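The control probe AT_W_M had a log2 signal of 9.50 in the wild-type pool and 9.18 in the knockout pool, while AT_W_3 and AT_W_5 lay below the background level on both arrays. The E1A spike-in probes over the filter had a median difference of 0.13 on the log2 scale in the direction of the knockout array. Their differences rose with signal from 0.07 to 0.26, except that the probe with the highest spike-in signal was equal on both arrays at 18.5. The value of 0.13 is thus not 1 offset that holds at every signal.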
